A study of Mus musculus with 8 samples.

How the data were processed

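RNA of 8 mouse BMM samples, WT or Cullin 3 KO and untreated or given LPS for 6 hours, was measured on 1-colour (Cy3) Agilent arrays, from 0.5 micrograms of RNA per sample per the labels' protocols. Groups and replicate numbers (2 per group) came from the sample titles. Per the file headers, the 8 arrays shared 1 slide and 1 scan, and the probe annotation gave positions on mm9.

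The spot intensity values were extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the processed signal intensity was corrected for background with a spatial surface, detrended within each array and given surrogate values for dim spots, with no scaling between arrays. The deposited value table held log2 values for 26670 of 55681 probes. Set against the scanner values of the same arrays, they differed from the log2 background-subtracted signal by a median of no more than 0.00214 and correlated with it at 0.996 or more. Their medians per array were 10.94, 11.10, 10.67, 10.73, 11.11, 11.03, 10.85 and 10.71 in the order WT untreated, WT LPS, KO untreated and KO LPS, each with replicates 1 and 2. The lowest value on each array stood for a signal of about 100. The table thus carried no scaling between arrays and no centring. The scale and centring were inferred from this match, and how its probes were selected stays unknown.

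For the main results, the log2 processed signal of non-control spots without an outlier flag was averaged per probe and reduced by the 75th percentile of each array. No spot was left out for saturation. A probe was kept if it was well above background on both arrays of at least 1 group, which left 39870 probes. Of the 55681 probes, 26056 were named through an accession of the reference gene table, 3200 through its symbols and 930 through its synonyms, and 25495 kept the name in the files. A gene was represented by its probe with the highest mean over the 8 arrays, giving 27950 genes, 447 of them with a missing array. Of 210 called pairs of a named gene and a comparison, 43 had more than 1 probe, and in 0 of them was another probe called the other way. In 2 of them, both for Slc1a2, the other probe had the opposite sign without being called. Values and bounds given for a gene are those of its chosen probe, and another probe could show a smaller change that was not called.

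The 5 comparisons were KO against WT without and with LPS, LPS against untreated in WT and in KO, and the difference between the LPS responses. One limma model with a mean per group was fitted to all 8 arrays, which then shared an estimate of the spread (4 residual and 2.29 prior degrees of freedom), with empirical Bayes moderation, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are log2 values with standard errors. Where a group was not well above background on either array, a fold is given as a lower bound, from the mean of the brighter group against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background, and such genes were ranked by the bound. Differences in response were not bounded, and the genes named with a called difference were well above background on all 8 arrays.

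A total of 36 gene lists was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. With the preset, 9, 12, 15, 16 and 9 lists were called in the 5 comparisons, in the order above, and with the estimated correlation 1, 1, 0, 0 and 0, the single list being the NRF2 targets. Fry, which tests whether a list's genes move one way and does not set them against other genes, called 19, 22, 34, 35 and 19. The text gives every shift called by camera for the genotype effects and the difference in response. For the LPS responses, where more lists were called, it gives 9 of them, chosen after their values were seen.

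Groups, gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took Cul3, the 10 largest rises and 10 largest falls among called genes with a bright group well above background on both arrays and groups that did not overlap (for the difference in response, with no rule on overlap), and up to 4 called members of each list by size of change or, where none was called, the member with the smallest p. Probe identifiers, accessions, clone names and RIKEN, Gm and LOC names were counted but passed over. The text drops some genes under this rule for length.

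Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited log2 values, no filter and a filter on all 8 arrays, each probe by itself, the mean of a gene's probes, only the 4 arrays of a comparison, the replicate number or the slide column as a block, trended and robust moderation, array weights, stricter thresholds, and leaving out each array. Added after seeing the data were scaling by 6 Agilent spike-in probes with a median signal over 500 on every array, the deposited values shifted by their 75th percentiles, and a replicate block with crossed KO numbers. The fit was tested on simulated data, with independent normal noise, the same spread for a gene in all groups and no LPS effect. The rates below hold for that setting and need not hold for these arrays. Of 100 genes changed 2-fold and 100 changed 4-fold among 27503, 27% and 83% were recovered for untreated KO against WT, with 0 unchanged genes called, and 3% and 57% for the difference in response, with 4 unchanged genes called. Tools were R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.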

Results

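Gene expression was measured in mouse bone marrow-derived macrophages (BMM). The cells had been grown from bone marrow for 6 days in medium conditioned by L929 fibroblasts, a source of the macrophage growth factor CSF1. They were wild type (WT) or knockout (KO) for Cullin 3 (Cul3), the scaffold of a family of ubiquitin ligases that mark proteins for degradation. They were left untreated or exposed for 6 hours to lipopolysaccharide (LPS), the cell-wall component of Gram-negative bacteria that activates Toll-like receptor 4. The 4 groups held 2 samples each, and each of the 8 samples was hybridised to 1 array of a single slide. The 75th percentile of the processed signal lay between 678 and 1557 per array, and 60.9% to 73.7% of the spots were well above background. Replicates correlated at 0.992 to 0.995 across genes, which are not independent replicates. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. All WT arrays lay in 1 row of the slide and all KO arrays in the other, so slide row and genotype cannot be told apart. Untreated and LPS arrays lay in separate columns of the slide, so column position and LPS cannot be told apart either. The mean log2 signal of the spike-in probes was 15.02 to 15.29 on the untreated arrays and lower on the LPS arrays. There it was 14.44 and 14.28 for WT and 14.69 and 14.72 for KO, so array brightness also differed by genotype with LPS. LPS separated the samples along the first principal component, which held 80.9% of the variance, and genotype along the second, with 7.87%.

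Cul3 itself was measured first, as a check on the genotype labels. Its single probe (A_52_P47645, chromosome 1, 80268109 to 80268168, mm9) was well above background on all 8 arrays. Relative to the 75th percentile of each array, its log2 level was 2.06 ± 0.03 (SD, n = 2) in untreated WT and 1.60 ± 0.07 in untreated KO cells, and 2.70 ± 0.02 in WT and 2.18 ± 0.05 in KO cells with LPS. Both KO samples lay below both WT samples in each state. Cul3 fell by 0.46 ± 0.11 (SE) in untreated KO cells, short of the threshold (limma, adjusted p = 0.0905), and fell by 0.52 ± 0.11 with LPS (adjusted p = 0.0304). The latter call ended when any 1 of the 8 arrays was left out (adjusted p 0.0523 to 0.140). The labels do not state which part of the gene was deleted, so it is not known whether this probe lies in it. The residual signal therefore does not measure how complete the loss was. With LPS, Cul3 rose by 0.64 ± 0.11 in WT (adjusted p = 0.00361) and by 0.58 ± 0.11 in KO cells (adjusted p = 0.00659). These rises depended on scaling. With arrays centred on their medians they were 0.25 (adjusted p = 0.171) and 0.29 (adjusted p = 0.144). In the authors' unscaled values Cul3 fell by 0.21 and dropped by 0.11. The LPS response of Cul3 did not differ detectably between genotypes (difference -0.06 ± 0.16, adjusted p = 0.865).

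**Figure D1:**
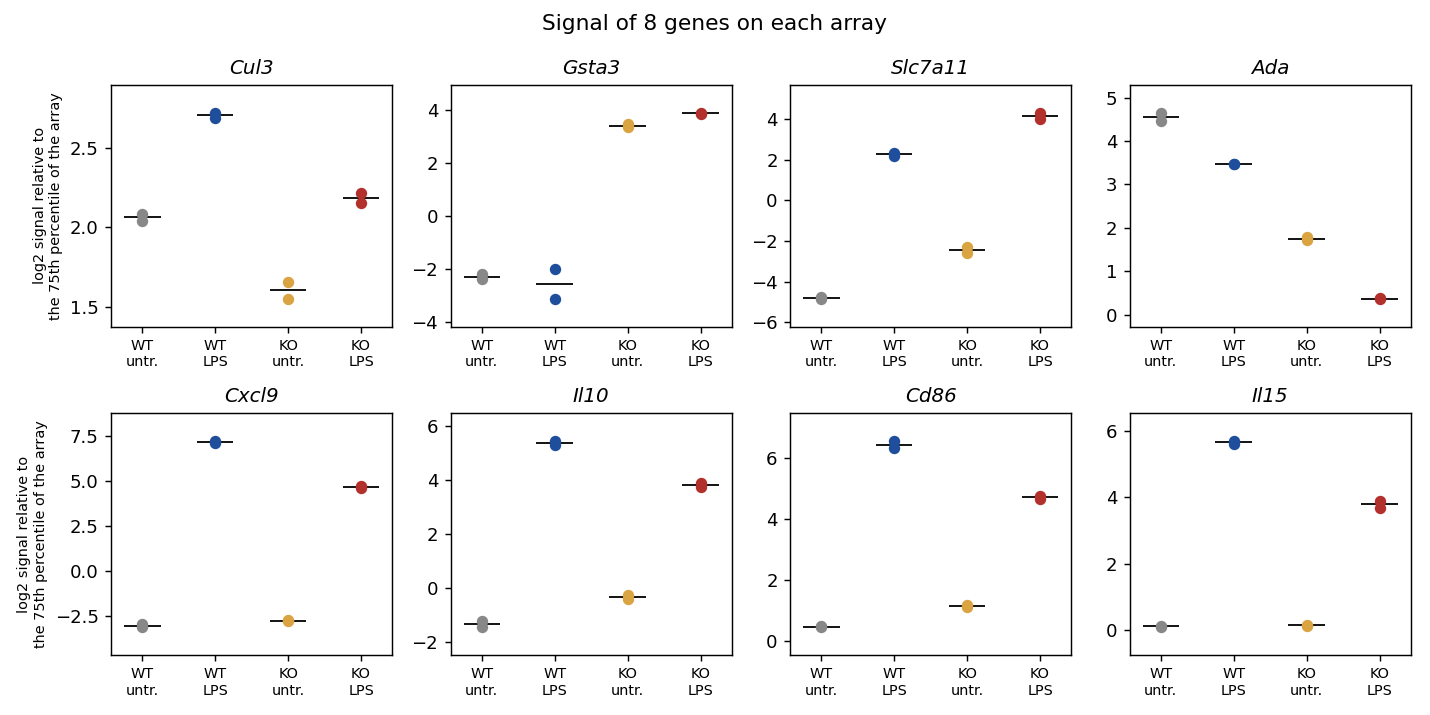
Log2 signal of 8 genes relative to the 75th percentile of each array (vertical axes, not starting at 0 and different in each panel) in the 4 groups, with a point per array and a line at the mean of 2 arrays. Cul3 is lower and Gsta3 higher in KO than WT samples in both states, while Cxcl9, Il10, Cd86 and Il15 rise with LPS in both genotypes to lower levels in KO cells.

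The comparison of untreated KO with untreated WT cells asked what loss of Cullin 3 changed before stimulation. Targets of NRF2, the transcription factor of the antioxidant response that Cullin 3 ligases normally degrade, shifted to higher levels in KO cells. Of 45 measured NRF2 targets, 16 rose and 0 fell, or 27 and 2 when adjusted over the list alone (camera adjusted p = 7.95e-14, and adjusted p = 0.0496 with an estimated correlation). The glutathione transferase Gsta3 rose by 5.68 ± 0.34 on the log2 scale (SE, n = 2 per group, adjusted p = 0.00137), the scavenger receptor Marco by 3.99 ± 0.27, the cystine transporter Slc7a11 by 2.34 ± 0.17 and the NADPH-producing malic enzyme Me1 by 2.26 ± 0.22. Nqo1 (2.23) and Gclm (2.25), chosen after their values were seen, rose as well.

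Markers of neutrophils were also higher in untreated KO cells, with 11 of 18 up and 0 down, or 14 up and 1 down over the list alone (camera adjusted p = 6.76e-11, and adjusted p = 0.216 with an estimated correlation). Retnlg rose by 3.77, with only 1 WT array well above background, the granule peptide Camp by 2.36, lactoferrin (Ltf) by 2.04 and the collagenase Mmp8 by 2.00. Among inflammatory cytokines, 5 of 23 rose and 0 fell, the same counts as over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.418 with an estimated correlation). They included Il1b (1.30), Il1a (1.27), Il10 (1.01) and Edn1. The last, the endothelin precursor, was not well above background in WT cells and was at least 3.92-fold higher. Arg1, which hydrolyses arginine, rose by 2.32 and coagulation factor F13a1 by 2.07. The alternative activation list that holds them did not shift (7 up and 4 down of 21, 9 and 4 over the list alone, camera adjusted p = 0.100). The fatty acid receptor Cd36 rose by 1.48 and the macrophage protein Cd5l by 1.65.

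Genes of G2/M and mitosis shifted down, with 4 of 35 lower and 0 higher, and 16 lower and 1 higher over the list alone (camera adjusted p = 0.000179, and adjusted p = 0.137 with an estimated correlation). The kinesin Kif4 fell by 1.48, cyclin Ccnb2 by a log2 change of -1.13 and the mitotic kinase Plk1 by a log2 change of -1.08. Of erythroid and megakaryocyte markers 4 of 12 rose (5 over the list alone, camera adjusted p = 0.0110, and adjusted p = 0.418 with an estimated correlation). Of stromal and endothelial markers 4 of 17 rose and 1 fell (8 and 1 over the list alone, camera adjusted p = 0.0373, and adjusted p = 0.418 with an estimated correlation). Pdgfrb (1.67), Cxcl12 (1.90, while its other probe was at 0.55 and not called) and Cdh5 (1.19) were among those that rose. Interferon-stimulated genes shifted up (2 up of 44, 3 over the list alone, camera adjusted p = 0.0108, and adjusted p = 0.634 with an estimated correlation). Antigen presentation genes shifted down (1 up and 1 down of 21, 2 up and 5 down over the list alone, camera adjusted p = 0.0268, and adjusted p = 0.355 with an estimated correlation). So did lysosomal genes (2 down of 28, as over the list alone, camera adjusted p = 0.00617, and adjusted p = 0.418 with an estimated correlation). The members that fell, Ctsk (-1.37) and Atp6v0d2 (-1.12), are also on the list of osteoclast markers, which did not shift (2 up and 3 down of 12, 3 and 4 over the list alone, camera adjusted p = 0.473). The antigen presentation and lysosomal shifts were not called with quantile normalization (adjusted p = 0.0582 and adjusted p = 0.0850). Fry called neither the interferon-stimulated genes (adjusted p = 0.154) nor the lysosomal genes (adjusted p = 0.0573). Of the 8 fits that each left out 1 array, 4 lost the shift of the cytokines, 4 that of the stromal and endothelial markers, 2 that of the interferon-stimulated genes, 2 that of antigen presentation and 1 that of the lysosomal genes. The costimulatory receptor Cd40 rose by 1.67 and the dendritic cell transcription factor Batf3 by 1.37.

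Among single genes, the transcript of the ROSA26 locus, Gt(ROSA)26Sor, had one of the largest rises in untreated KO cells (6.67 ± 0.35, adjusted p = 0.00118). The alcohol dehydrogenase Adh7 and the natural killer receptor gene Klra8 were not well above background in WT cells and were at least 18.9-fold and at least 33.3-fold higher. Slc16a9 (5.73), the lectin receptor Cd209f (5.08) and thrombospondin Thbs1 (4.18) were also among the largest rises. Among the largest falls, Dnajb3 was at least 15-fold lower and the anion exchanger Slc4a3 fell by 3.13. The other Slc4a3 probe was at -0.86 and not called. Adenosine deaminase Ada fell by a log2 change of -2.80, deiodinase Dio2 by one of -2.60 and the growth factor receptor Kit by one of -2.39. In all, 960 of 27950 genes were called, 633 higher and 327 lower (limma, adjusted p under 0.05). That split depended on the values used. It was 1250 higher and 1063 lower with normexp background correction, 1234 and 343 with the authors' unscaled values, and 635 and 1067 when those were shifted by their 75th percentiles. The count was 264 without WT untreated replicate 1, 156 without its replicate 2, 144 without KO untreated replicate 1 and 118 without its replicate 2. It was 1509, 1511, 483 and 488 without WT LPS replicates 1 and 2 and KO LPS replicates 1 and 2, which enter through the shared estimate of the spread. With slide column as a block, 136 genes were called.

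With LPS, KO cells again had higher NRF2 targets than WT cells and had lower levels of many inducible immune genes. Of the 45 NRF2 targets, 27 rose and 1 fell (29 and 2 over the list alone, camera adjusted p = 2.35e-15, and adjusted p = 0.0406 with an estimated correlation). Gsta3 rose by 6.43 ± 0.34 (adjusted p = 0.000937), and Gsta1, Gsta2 and the aldehyde oxidase Aox1, none of them well above background in WT cells with LPS, were at least 14.5-fold, 6.45-fold and 3.45-fold higher. Of 44 interferon-stimulated genes 24 fell and 0 rose (39 and 0 over the list alone, camera adjusted p = 7.99e-13, and adjusted p = 0.354 with an estimated correlation). The nucleotide kinase Cmpk2 fell by 1.81 ± 0.27, Ifit2 by a log2 change of -1.66, the GTPase Iigp1 by one of -1.55 and the transcription factor Irf8 by one of -1.37. Interferon beta itself (Ifnb1) fell by 2.57 ± 0.49 (adjusted p = 0.0190).

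**Figure D2:**
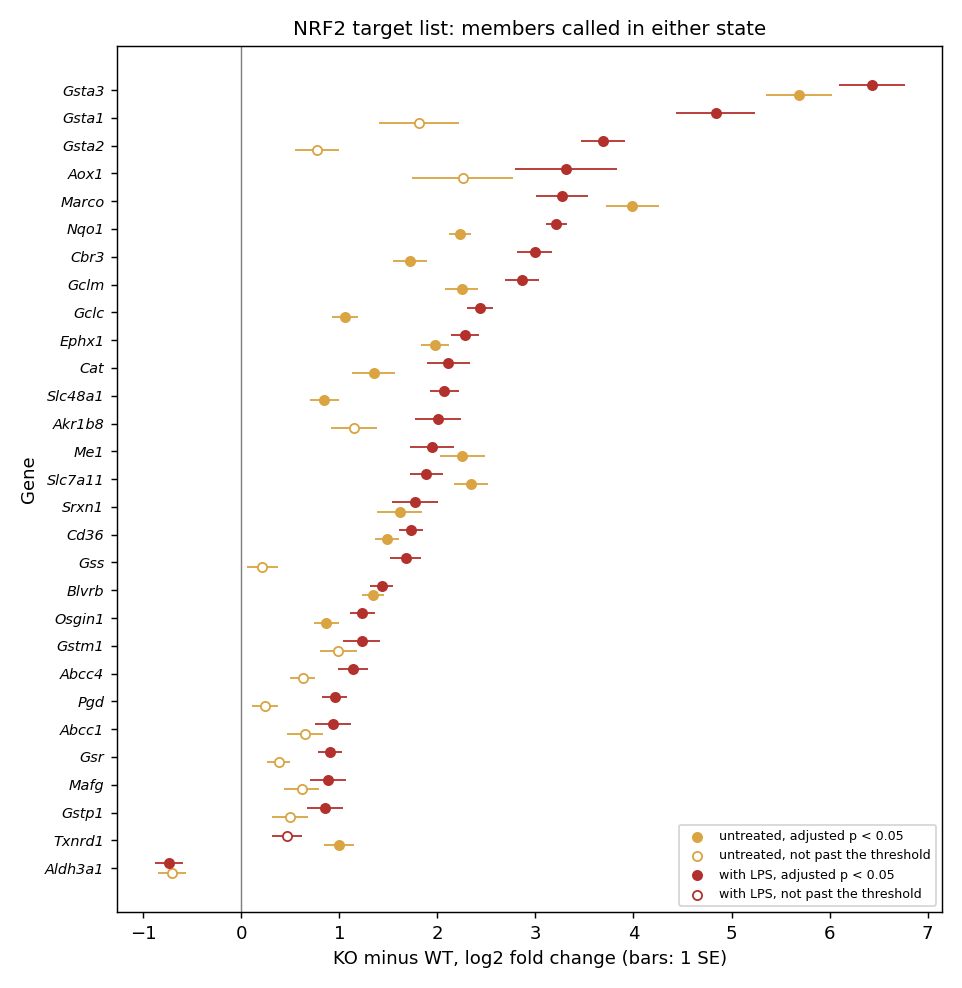
KO minus WT log2 fold change (horizontal axis, bars 1 SE, n = 2 per group) of the NRF2 targets called in untreated cells or with LPS (rows), where filled points passed an adjusted p under 0.05. All but Aldh3a1 lie to the right of 0 in both states, and the values of Gsta1, Gsta2 and Aox1 are fits against signals not well above background.

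The inflammatory cytokine list shifted down in KO cells with LPS, with 10 of 23 down and 1 up (12 and 1 over the list alone, camera adjusted p = 1.17e-05, and adjusted p = 0.195 with an estimated correlation). Il33 fell by 2.14, Il15 by a log2 change of -1.87, Il27 by one of -1.80 and Edn1 by one of -1.79. Of 22 chemokines 8 fell and 5 rose (12 and 5 over the list alone, camera adjusted p = 0.0262, and adjusted p = 0.563 with an estimated correlation). The T cell attractants Cxcl9 and Ccl17 fell by 2.49 and by a log2 change of -2.36, and Ccl12 by one of -2.23, while the neutrophil attractant Cxcl5 rose by 2.63. The chemokine shift was not called with quantile normalization (adjusted p = 0.226) or normexp (adjusted p = 0.108). The list of negative regulators of Toll-like receptor signalling shifted down (11 of 29 down and 1 up, 19 and 1 over the list alone, camera adjusted p = 8.63e-06, and adjusted p = 0.195 with an estimated correlation). The transcription factors Klf4 (-1.54) and Atf3 (-1.54) and the mRNA-destabilising protein Zfp36 (-1.38) were among them. The antigen presentation list shifted down (9 of 21 down and 0 up, 16 and 0 over the list alone, camera adjusted p = 3.68e-06, and adjusted p = 0.0929 with an estimated correlation). The costimulatory molecules Cd86 (-1.74) and Cd40 (-0.97) and the class II genes H2-Aa (-1.18) and H2-Eb1 (-1.03) were lower. Dendritic cell markers fell in 6 of 14 cases with 0 up (8 and 0 over the list alone, camera adjusted p = 0.00334, and adjusted p = 0.195 with an estimated correlation).

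The lists of cholesterol synthesis, lipid handling and glycolysis shifted up in KO cells with LPS, with fewer of their members called than not. Cholesterol synthesis genes rose in 7 of 24 cases and fell in 1 (9 and 2 over the list alone, camera adjusted p = 0.00334, and adjusted p = 0.195 with an estimated correlation). The sterol carrier Stard4 (2.25) and the mevalonate pathway enzyme Mvd (1.83) were higher. The list of LXR targets and lipid handling had 7 up and 3 down of 23 (8 and 4 over the list alone, camera adjusted p = 0.0337, and adjusted p = 0.195 with an estimated correlation). The desaturase Scd2 was higher by 2.62 and fatty acid synthase Fasn at least 2.90-fold. Glycolysis and HIF-1 targets had 7 up and 2 down of 30 (11 and 2 over the list alone, camera adjusted p = 0.0286, and adjusted p = 0.195 with an estimated correlation). The lysosomal list shifted down (7 of 28 down and 1 up, 10 and 1 over the list alone, camera adjusted p = 0.000405, and adjusted p = 0.354 with an estimated correlation). The proton pump subunit Atp6v0d2 was at -1.98 and the protease Ctsk at -1.85, and both are also on the list of osteoclast markers (3 up and 3 down of 12, 4 and 5 over the list alone, camera adjusted p = 0.793). The lysosomal shift was not called with quantile normalization (adjusted p = 0.116). Leaving out 1 array ended the shift of the LXR list in 2 of 8 fits, that of the glycolysis list in 2 and that of the chemokines in 1. Neutrophil markers were again higher (12 of 18 up and 1 down, 12 and 2 over the list alone, camera adjusted p = 2.99e-06, and adjusted p = 0.195 with an estimated correlation). The gelatinase Mmp9 (2.15) and Chil1 (2.06) rose.

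The largest rises in KO cells with LPS included Adh7 (at least 82.3-fold), Slc16a9 (5.75, with 1 WT array well above background), Gt(ROSA)26Sor (5.44), the glycine transporter Slc6a9 (4.41), Tmem119 (3.65) and the phospholipase Pla2g7 (3.50). The largest falls included Glrp1 (-3.93), Dnajb3 (-3.89), the cytokine Tnfsf18 (-3.58), the serpins Serpina3f (-3.12) and Serpina3i (-3.11), Ada (-3.09) and the interferon-induced Ifit1bl1 (-3.01). In all, 4605 genes were called, 2207 higher and 2398 lower (limma, adjusted p under 0.05). The split was 3678 and 727 with the authors' unscaled values and 2300 and 3802 with normexp, and quantile normalization put more genes higher than lower (2476 and 2066). The median over all genes was -0.08 here, 0.25 with the unscaled values and -0.17 with normexp. The count was 1775 without KO LPS replicate 1, 1502 without its replicate 2, and 2751 and 2744 without KO untreated replicates 1 and 2. It was 1154 with slide column as a block and 808 when fitted on the 4 arrays compared.

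Genotype effects in the absence and presence of LPS overlapped. Of the genes called in both, 300 were higher in KO cells in both states and 178 lower in both, against 50 and 28.1 for independent lists, and 54 changed in opposite directions, against 80.1. These counts for independent lists are a rough guide only, since both lists come from 1 fit that shares the spread of each gene, which by itself makes genes of low spread more often called in both. Edn1 was one of these, higher in untreated and lower in LPS-treated KO cells. Marco, Gsta3, Adh7, Slc16a9 and Gt(ROSA)26Sor were higher in both states, and Dnajb3 and Ada were lower in both. The 478 genes with the same direction became 143, 98, 81, 72, 178 and 177 without WT untreated replicates 1 and 2, KO untreated replicates 1 and 2 and KO LPS replicates 1 and 2. Across genes, which are not independent replicates, the 2 effects correlated with r = 0.296 and rho = 0.245, and they share no arrays.

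In WT cells, LPS raised cytokines, chemokines and interferon-stimulated genes and lowered cell cycle and sterol synthesis genes. Il6 rose by 14.28 ± 0.79 on the log2 scale, with 1 untreated array well above background, and Il1a by 12.97, Il12b by 12.90 and the prostaglandin synthase Ptgs2 by 12.08. Edn1 and Il19 were not well above background in untreated cells and were at least 9682-fold and at least 17362-fold higher. The bound for Il19 holds for the chosen probe, and its other probe rose by 11.86 on the log2 scale. Of 23 inflammatory cytokines 22 rose and 0 fell, the same over the list alone (camera adjusted p = 1.42e-11, and adjusted p = 0.0966 with an estimated correlation). Of 22 chemokines 20 rose and 1 fell, the same over the list alone (camera adjusted p = 1.48e-08, and adjusted p = 0.178 with an estimated correlation). Ccl12 rose by 11.26 and Cxcl9 by 10.19. All 44 interferon-stimulated genes rose, also over the list alone (camera adjusted p = 3.44e-18, and adjusted p = 0.180 with an estimated correlation). Gbp5 (9.83) and Mx1 (8.01) were among the largest, and Ifnb1 was at least 176-fold higher. Of 29 negative regulators 24 rose and 2 fell, the same over the list alone (camera adjusted p = 1.09e-07, and adjusted p = 0.115 with an estimated correlation). The interleukin-1 receptor antagonist Il1rn rose by 8.96 and Socs1 by 8.08. Nitric oxide synthase Nos2 rose by 9.99.

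Cholesterol synthesis genes fell in WT cells with LPS (19 of 24 down and 1 up, the same over the list alone, camera adjusted p = 1.09e-07, and adjusted p = 0.0966 with an estimated correlation). Dhcr7 (-4.22), Sqle (-3.81) and Stard4 (-4.71) were among them. G1/S and DNA replication genes fell in 24 of 40 cases and rose in 9 (24 and 10 over the list alone, camera adjusted p = 1.16e-05, and adjusted p = 0.180 with an estimated correlation). E2f2 was at -4.66 and the replication licensing helicase Mcm2 at -4.35. Of 35 G2/M genes 25 fell and 6 rose, the same over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.0966 with an estimated correlation). Glycolysis and HIF-1 targets rose in 24 of 30 cases and fell in 2, the same over the list alone (camera adjusted p = 0.000321, and adjusted p = 0.0966 with an estimated correlation). Pfkfb3 (5.54), Adm (5.60) and the glucose transporter Slc2a1 (4.09) rose. Proteasome subunits rose in 20 of 26 cases, the same over the list alone (camera adjusted p = 0.00194, and adjusted p = 0.422 with an estimated correlation). That shift was not called with quantile normalization (adjusted p = 0.533) or normexp (adjusted p = 0.0570). The largest falls included Arhgap19 (at least 135-fold by the chosen probe, with the other called at -4.80), Sesn1 (-7.03) and Rasgrp3 (-6.74). The myeloid transcription factor Cebpa fell by 5.11. In all, 16309 genes were called, 10204 higher and 6105 lower (limma, adjusted p under 0.05). The split followed the scaling, with 6997 higher and 8562 lower with quantile normalization, 6323 and 8464 with median centring, 2450 and 8537 with the authors' unscaled values and 3779 and 6763 when those were shifted by their 75th percentiles. It was 8288 and 6807 with spike-in scaling, and 16500 and 5549 with normexp, further toward higher. The median over all genes was 0.32 here, 0.52 with normexp, 0.16 with spike-in scaling, -0.06 with quantile normalization and -0.60 with the unscaled values.

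In KO cells, LPS changed the same lists in the same directions. Of the 23 cytokines 22 rose and 0 fell (23 over the list alone, camera adjusted p = 5.87e-13, and adjusted p = 0.0688 with an estimated correlation). Il1a rose by 11.07, Il6 by 10.98, Il12b by 10.77 and Il19 by 12.01. Of 22 chemokines 20 rose and 1 fell, the same over the list alone (camera adjusted p = 7.10e-10, and adjusted p = 0.162 with an estimated correlation). Cxcl3 rose by 11.88. Of the interferon-stimulated genes 43 rose, also over the list alone (camera adjusted p = 1.86e-19, and adjusted p = 0.162 with an estimated correlation). Gbp5 rose by 8.44 and Gbp2 by 7.19, and Ifnb1 was at least 25.6-fold higher. The difference between the LPS responses of Ifnb1 was not called (-2.35 ± 0.69, limma adjusted p = 0.116). Negative regulators rose in 24 cases and fell in 3, the same over the list alone (camera adjusted p = 8.08e-08, and adjusted p = 0.136 with an estimated correlation). Cholesterol synthesis genes fell in 20 cases (21 over the list alone, camera adjusted p = 2.50e-08, and adjusted p = 0.0688 with an estimated correlation). G1/S genes fell in 26 (27 over the list alone, camera adjusted p = 9.50e-08, and adjusted p = 0.162 with an estimated correlation), as did G2/M genes in 26 (26 over the list alone, camera adjusted p = 2.48e-05, and adjusted p = 0.0688 with an estimated correlation). Glycolysis and HIF-1 targets rose in 26 (26 over the list alone, camera adjusted p = 2.74e-06, and adjusted p = 0.0688 with an estimated correlation). Proteasome subunits rose in 16 (16 over the list alone, camera adjusted p = 0.00176, and adjusted p = 0.437 with an estimated correlation), the latter not called with quantile normalization (adjusted p = 0.211). The NRF2 targets Slc7a11 and Gsr rose by 6.62 and 2.99, and Gsta1 by 3.91. Slc7a11 rose in WT cells as well, by 7.07. Gsr also rose there, from log2 levels of 3.86 and 4.03 on single arrays to 6.36 and 6.44. The NRF2 target Cbr3 fell in WT cells by a log2 change of -2.53. In KO cells its levels went from 5.48 and 5.66 to 4.38 and 4.24. Sesn1 fell by 6.27, as did the acyl-CoA thioesterase Acot1 (-6.27). In all, 13709 genes were called, 8011 higher and 5698 lower (limma, adjusted p under 0.05). The split was 5909 and 7585 with quantile normalization, 5283 and 7501 with median centring, 6143 and 6550 with spike-in scaling, and 2186 and 7577 with the authors' unscaled values. It was 3790 and 5665 when those were shifted by their 75th percentiles, and 14187 and 5427 with normexp. The median over all genes was 0.21, against 0.38 with normexp, 0.04 with spike-in scaling, -0.06 with quantile normalization and -0.48 with the unscaled values.

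The 2 LPS responses correlated across genes with r = 0.899 and rho = 0.825, genes not being independent replicates. Of 11682 genes called in both genotypes, 11564 changed in the same direction. Over the 18336 genes called in either, the slope of the KO on the WT response (principal axis) was 0.860, and 0.841 to 0.873 over the 16 combinations of single arrays. It was 0.866 (0.807 to 0.917) over the 11309 genes raised and 0.937 (0.880 to 0.962) over the 7027 lowered, ranges that overlap, and the lowered genes had the higher slope in all 16 combinations, which share arrays. Of the genes called in either, 68.8% had the smaller change in KO cells, and 67.2% with quantile normalization, 68.3% with median centring, 72.2% with normexp and 68.0% with spike-in scaling, checked after the first value was seen.

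**Figure D3:**
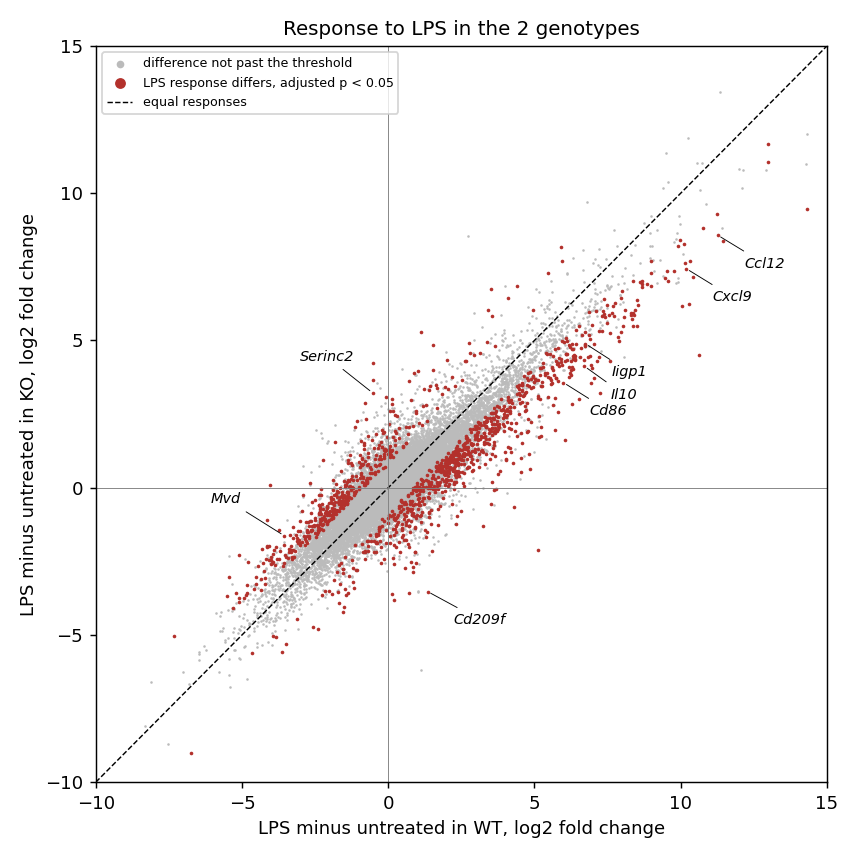
Log2 fold change with LPS in WT (horizontal axis) and KO cells (vertical axis) for each of 27950 genes, with red points where the difference between the responses passed an adjusted p under 0.05 and a dashed line for equal responses. Cxcl9, Ccl12, Il10, Iigp1 and Cd86 lie below the line, and Mvd and Serinc2 above it.

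The difference between the LPS responses was tested directly as an interaction. Several cytokine and interferon-stimulated genes rose less in KO than in WT cells, and several NRF2 targets moved more toward higher levels in KO cells. The slope of 0.866 over all raised genes by itself gives lists of strongly raised genes a lower response in KO cells. The shifts of such lists are therefore not separate from that slope, and whether they go beyond it was not tested. Of 23 cytokines 12 had a lower response in KO cells and 0 a higher one (16 and 1 over the list alone, camera adjusted p = 2.23e-08, and adjusted p = 0.189 with an estimated correlation). The anti-inflammatory Il10 (-2.57 ± 0.20, adjusted p = 0.00976) and Il15 (-1.90 ± 0.18) were 2 of them. Of 44 interferon-stimulated genes 13 had a lower response and 0 a higher one (33 and 0 over the list alone, camera adjusted p = 4.49e-16, and adjusted p = 0.296 with an estimated correlation). Iigp1 (-1.84), the transcription factor Irf1 (-1.53) and the RNA sensor Ifih1 (-1.51) were 3 of them. Of 29 negative regulators 10 were lower and 0 higher (20 and 1 over the list alone, camera adjusted p = 3.86e-07, and adjusted p = 0.189 with an estimated correlation). Nfkbiz was at -1.79 and Atf3 at -1.47. Of 22 chemokines 6 were lower and 1 higher (12 and 3 over the list alone, camera adjusted p = 0.00599, and adjusted p = 0.424 with an estimated correlation). Cxcl9 was at -2.75 and Ccl12 at -2.68. Dendritic cell markers were lower in 4 of 14 cases (9 over the list alone, camera adjusted p = 0.000471, and adjusted p = 0.189 with an estimated correlation). Batf3 was at -2.24, with a log2 change of -1.85 with LPS in KO cells and no called change in WT cells (0.38, limma adjusted p = 0.0652). Alternative activation genes were lower in 2 of 21 cases (6 over the list alone, camera adjusted p = 0.00483, and adjusted p = 0.296 with an estimated correlation). These were Ccl17 (-2.32) and the interleukin-4 receptor Il4ra (-1.48). Antigen presentation genes were lower in 3 of 21 (3 over the list alone, camera adjusted p = 0.0375, and adjusted p = 0.279 with an estimated correlation). Cd40 was at -2.64, a difference made up of its higher level in untreated KO cells (1.67) and its lower level with LPS (-0.97), and Cd86 was at -2.42. NRF2 targets had a higher response in 7 of 45 cases and a lower one in 0 (8 and 0 over the list alone, camera adjusted p = 0.00157, and adjusted p = 0.189 with an estimated correlation). The glutathione synthesis enzymes Gss (1.46) and Gclc (1.38) were among them. The G2/M list shifted up (1 higher and 2 lower of 35, 6 and 4 over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.271 with an estimated correlation). The chemokine, antigen presentation and G2/M shifts were not called with quantile normalization (adjusted p = 0.105, adjusted p = 0.311 and adjusted p = 0.183). The antigen presentation shift was also lost with normexp (adjusted p = 0.0736), spike-in scaling (adjusted p = 0.0624) and the replicate block (adjusted p = 0.0575), and the G2/M shift with normexp (adjusted p = 0.156). Leaving out 1 array ended the chemokine, antigen presentation and G2/M shifts in 1, 4 and 4 of 8 fits.

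Single genes with a higher response in KO cells included Serinc2 (3.75 ± 0.30), with the lowest of its 3 probes at 1.20 and 1 other probe called. The glutamate transporter Slc1a2 (3.23, while its other probe was at -1.83 and not called), Susd2 (3.16), pyruvate carboxylase Pcx (2.33) and Mvd (1.93) were others. Cd209f had a lower response (-4.87). In all, 1257 genes were called, 440 with a higher and 817 with a lower response in KO cells (limma, adjusted p under 0.05). The split was 563 and 688 with quantile normalization, 398 and 471 with median centring 447 and 377 with the authors' unscaled values and 1202 and 805 when those were shifted by their 75th percentiles. With normexp it was 825 and 1629 and with spike-in scaling 207 and 554. These calls depended on single arrays. No gene (0) was called by limma without WT untreated replicate 1 (5583 at an unadjusted p under 0.05) and 0 without KO LPS replicate 2 (5043 at an unadjusted p under 0.05). The count was 1, 68, 5 and 92 without WT untreated replicate 2, KO untreated replicates 1 and 2 and KO LPS replicate 1, and 2326 and 442 without WT LPS replicates 1 and 2. With slide column as a block, limma called 0 genes, with 4402 at an unadjusted p under 0.05.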

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

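The tests of array scaling and of slide position were chosen after the results were seen, and the spike-in test was set down before its result was known. The LPS response differed between genotypes by the interaction test for 1257 genes, and these calls depended on single arrays and were lost with slide column as a block, as given above. Among the genes named, KO minus WT differences in the log2 response were -2.57 for Il10, -2.64 for Cd40, -2.75 for Cxcl9, -2.68 for Ccl12, -2.42 for Cd86, -1.90 for Il15, -2.32 for Ccl17, -2.24 for Batf3, -1.51 for Ifih1, -1.53 for Irf1, -1.84 for Iigp1, -1.48 for Il4ra, -1.79 for Nfkbiz, -1.47 for Atf3 and -4.87 for Cd209f. They were 1.38 for Gclc, 1.46 for Gss and 3.75 for Serinc2 (1.20 for the lowest of its 3 probes). They were 3.23 for Slc1a2 (-1.83 for its other probe, not called), 3.16 for Susd2, 1.93 for Mvd and 2.33 for Pcx. Camera adjusted p-values for the difference were 0.00157 for NRF2 targets, 2.23e-08 for inflammatory cytokines, 0.00599 for chemokines, 3.86e-07 for negative regulators, 4.49e-16 for interferon-stimulated genes, 0.00483 for alternative activation, 0.0375 for antigen presentation, 0.0346 for G2/M genes and 0.000471 for dendritic cell markers, and none passed with an estimated correlation.

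The smaller LPS response of KO cells, with a slope of 0.860 on the WT response (0.866 for raised and 0.937 for lowered genes), was weighed against technical explanations. Compressed signals on the KO LPS arrays would flatten the spike-in series as well. The slope of the spike-in log2 signals, KO LPS on WT LPS arrays, was 0.975 (95% interval 0.953 to 0.998, 0.966 to 0.983 over pairs of arrays, 6 probes). It was also 0.975 for untreated arrays. Over the range of these probes, all above 500, that is too close to 1 to account for 0.860, though a small part stays open. The median spot of each array was dimmer (32.8 to 60.9), and compression at such signals was not tested. Scaling by a shift of each array alters which genes are called in either genotype (18336 here, 17114 with spike-in scaling). Over a fixed set of genes it cannot change the slope of 0.860. Quantile normalization, which can, left it at 0.865, so unequal signal distributions do not account for it. The row of the slide cannot be told apart from genotype, because each genotype lies in 1 row, so for the slope of 0.860 an effect of row stays open. An effect of Cullin 3 loss, or a different mix of cells in the KO cultures, may also account for the slope of 0.860, and neither was tested apart from the row.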

How the results depend on the processing

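The spike-in, shifted-table and crossed-block settings were chosen after seeing the data. Cul3 aside, all 207 pairs of a named gene and a comparison kept their direction in every alternative run, and 136 kept their call in all of them; these runs follow the probe chosen for each gene. Of 48 list shifts described, 9 lost their call with quantile normalization, 4 with normexp, 1 with spike-in scaling, 1 with the replicate block, 2 with fry and 46 with an estimated correlation. Leaving out 1 array ended a call in 27 of 384 fits, for 11 of the shifts, and moved the count of members called by more than 1.5-fold in 56 of 200 fits for members higher and 88 of 184 for members lower. Counts of called genes for KO against WT untreated were 2313 with normexp, 1577 with the authors' values, 1702 with these shifted, 388 with no filter, 563 on the 4 arrays, 375 with the replicate block, 136 with slide column as a block, 1896 with a trend, 2561 with array weights, 639 at 2-fold and 202 at an adjusted p under 0.01. With LPS they were 2865 with no filter, 808 on the 4 arrays, 2817 with the replicate block, 1154 with slide column, 2699 with array weights, 1999 at 2-fold and 1329 at 0.01. For LPS in WT they were 10542 with the shifted table and 10176 at 2-fold, and in KO 8158 at 2-fold. For the difference in response they were 2454 with normexp, 824 with the authors' values, 2007 with these shifted, 761 with spike-in scaling, 197 with no filter, 132 with the replicate block, 0 with slide column (limma, 4402 at an unadjusted p under 0.05), 2291 with a trend and 32 at 0.01. The Cul3 fall with LPS lost its call with median centring (-0.48), the authors' values (-0.17), no filter and the replicate block (both -0.52). Its rise lost its call with median centring (0.25 in WT, 0.29 in KO) and turned with the authors' values (-0.21 and -0.11), and its uncalled difference in response turned with quantile normalization (0.049), median centring (0.031) and the authors' values (0.10). The correlation of LPS responses was 0.937 with normexp and 0.929 with the filter on all arrays. The overlap of genotype effects was 1070 with normexp and 190 with the replicate block. Fewer genes were tested with the authors' values, fewer arrays entered the 4-array fits, and thresholds act by construction; for the others the cause was not tested.

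Leaving out 1 array, which leaves a lone sample assumed to vary like the other groups, gave 118 to 1511 genes for KO against WT untreated, 1502 to 4249 with LPS, 12766 to 15879 for LPS in WT, 10036 to 14815 in KO and 0 to 2326 for the difference. Cul3 ranged from -0.51 to -0.41 untreated, -0.55 to -0.49 with LPS, 0.62 to 0.66 for LPS in WT, 0.53 to 0.63 in KO and -0.11 to -0.01 for the difference. The correlation ranged from 0.878 to 0.898, the slope from 0.840 to 0.868 and the overlap from 72 to 658. Across genes, the differences between replicates 1 and 2 of the groups correlated at -0.186 to 0.0245, with no sign that same-numbered samples rose or fell together. These values cannot show whether same-numbered samples share animals or cultures. Same-numbered WT and KO arrays of a state did share a slide column. Crossing the KO numbers gave 4107 genes for KO against WT with LPS.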

Other observations

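The tests of DNA near Cul3 and ROSA26 were chosen after the pattern was seen, and those of Lyz2 and of the second marker lists were set down before their results were known.

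Cell cycle genes differed in KO cells with LPS as well, with no shift of their lists. Of 40 G1/S genes 8 rose and 10 fell (camera adjusted p = 0.793), with cyclin Ccnd1 at -2.05 and the replication factor Mcm10 at -1.81, and of 35 G2/M genes 1 rose and 8 fell (camera adjusted p = 0.744), with Tpx2 at -2.23 and the kinesin Cenpe at -2.06. The transcription factor Irf4 was lower by a log2 change of -1.80, Arg1 was higher by 2.57, and Tfeb, a regulator of lysosomal genes, was higher by 0.94 while Ctsk was lower. In untreated KO cells 2 genes of serine and one-carbon metabolism on the list of the unfolded protein response and ATF4 targets were lower, Phgdh at -1.20 and the folate enzyme Mthfd2 at -0.72, and Chac1 was at -1.36. Slc7a11, on the same list, was higher by 2.34, and camera did not call a shift of that list.

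Some genes with large genotype effects were Dnajb3 and Slc4a3 (by 1 of its 2 probes when untreated) near Cul3 on chromosome 1, and Gt(ROSA)26Sor on chromosome 6. They raised the hypothesis that DNA carried along with engineered alleles may set part of the genotype effect. Genes called the same way in both states made up 2.30% of 434 genes within 10 Mb of Cul3 or Gt(ROSA)26Sor and 1.70% of 27259 elsewhere, an odds ratio of 1.36 (95% interval 0.645 to 2.56, Fisher's exact test, two-sided p = 0.345), and 0 of 263 bins of 10 Mb passed an adjusted p under 0.05 by a hypergeometric test, with 7 of 122 genes in the bin with the smallest p. Taken alone, the window at Cul3 held 7 of 235 (2.98%, odds ratio 1.78, 95% interval 0.702 to 3.75, Fisher's exact test, two-sided p = 0.127) and that at Gt(ROSA)26Sor 3 of 199 (odds ratio 0.886, 95% interval 0.180 to 2.64). The 7 genes near Cul3 include Dnajb3 and Slc4a3, which had raised the hypothesis, so that count is not independent of the pattern. In the 10 Mb bin that holds Cul3, 1 of 119 genes was called the same way in both states. The tests did not detect gathering, and their intervals leave it open. An engineered allele at Lyz2 was a second candidate explanation, and Lyz2 changed by -0.25 (95% interval -0.70 to 0.20) in untreated KO cells and by -0.12 (-0.49 to 0.24) with LPS. A loss of 0.5, the size set for the test in untreated cells, lay within the first interval and just outside the second. The preset test therefore does not decide, and such an allele stays open. The rise of Gt(ROSA)26Sor itself, on 4 of 4 KO arrays, has no test here that bears on its origin.

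Higher neutrophil markers in untreated KO cells, and the higher members of the joint stromal and endothelial list, may reflect other cells in the cultures. Among neutrophil genes outside the rule for named genes, S100a9 rose by 1.70 and S100a8 by 1.62, while Elane, at 5.30 in WT, was at -0.61 (limma adjusted p = 0.115). In a second neutrophil list 7 of 16 genes were called higher, a share of 0.438 (95% interval 0.198 to 0.701), and in a second endothelial list 2 of 9, a share of 0.222 (0.0281 to 0.600), with Vwf lower at -0.96. The median change was 0.611 over the second neutrophil list, with 13 of 16 genes positive. It was 0.0567 over the second endothelial list, with 6 of 9 positive, close to the 0.0518 over all genes. Neither share decides, and a change of gene activity within macrophages cannot be told apart from other cells for either list.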
